A study of Caenorhabditis elegans with 2 samples.

How the data were processed

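The data were processed peak lists from chromatin immunoprecipitation of EFL-1 with a C-terminal GFP-FLAG tag, in 2 biological replicates of whole young adult hermaphrodites of strain YL479, per the labels. Both samples formed 1 group. The labels name a possible control experiment, which was not analysed here.

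Lists were deposited on builds ce10 and ce11, per the descriptions deposited with the files: 30000 candidate peaks with background for each replicate and for the pool, meant as input for the irreproducible discovery rate (IDR), and 1 optimal IDR-thresholded list derived from them. The candidate lists of each replicate were therefore called per sample and the pooled list on both replicates. The aligner, the peak caller, their versions, the IDR threshold and the treatment of reads with several matches are not given in the sources used here. The signal value of each peak is the authors' own, as deposited, on a scale that is not stated, and was used to describe and rank peaks within a list. The deposited −log10 q-value reached its ceiling of 3.70 in all 2207 IDR-thresholded peaks and was therefore not used for ranking. The files give no read counts, so depth is unknown and precision is given from the number of peaks or genes: intervals on shares are 95% Wilson intervals and cover counting error only.

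Positions were compared with the WBcel235 genome, which is the same assembly as ce11, and with Ensembl release 115 gene models. Lists on ce10 were used for numbers of peaks, the share on X and the agreement and signal correlation of replicates, and no coordinates were converted. The 28 peaks on the mitochondrial genome were left out of all results but the number of peaks, so the number of top candidates compared between replicates was 2179. Coordinates are given from base 1.

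A gene start was the first base of any protein-coding transcript of a protein-coding gene, and a gene was bound if a summit lay within 500 bp of a start. Peaks farther away were classed in the order coding exon, untranslated exon, intron and intergenic. Overlap of at least 1 bp counted as shared between replicates. Shares near starts and shared peaks were compared with 1000 random placements within chromosomes (one-sided permutation). Motifs were searched on both strands in windows of 100 bp either side of the summit and compared with pooled candidates that overlap no IDR-thresholded peak, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 4 strings (E2F, CHR and the reversed string of each). Words of 6 bases were compared with windows centred 500 bp to each side, adjusted over 2080 words. The difference in log2 signal between peaks with and without the E2F sequence was tested with 100000 permutations across peaks, which are not independent replicates.

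Gene lists were tested by two-sided Fisher's exact tests against all other nuclear protein-coding genes, adjusted over 22 lists, and again against the 7583 genes with a pooled candidate within 500 bp of a start. Genes that share a divergent start share a peak and are not independent. The names sld-3, pold-1 and cde-1 matched no gene in the annotation. The lists covered DREAM and E2F factors, cell cycle control, DNA replication, DNA repair, mitotic segregation, meiosis, oocyte and maternal factors, germ granules, germline stem cell regulators, apoptosis, chromatin regulators, the proteasome, cytosolic and mitochondrial ribosomal proteins, sperm, histones, intestine, muscle, neurons, neuropeptides, collagens and chemoreceptors.

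The samples, tests, lists, main settings and most alternatives were fixed before the data were examined. The same holds for the rule by which genes are named: those nearest to the 20 strongest peaks if within 500 bp, the bound members with the 4 highest signal values in each list, every member of the DREAM and E2F list, and efl-1 and unc-119. One chemoreceptor gene that the rule names is not reported here. Genes that share a named peak, tRNA and other noncoding genes were added after the values were seen. Alternatives were another build, the stronger 50% of the peaks, each replicate alone, other overlaps, distances, windows and backgrounds, and the nearest start alone. Leaving out peaks, or peaks and candidates, within 100 bp of a tRNA gene, stratifying motif tests by GC content in 10 groups and counting nuclear peaks alone were chosen after seeing the data.

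The main statistics were tested on simulated data, apart from the correlation of replicate signal and the shares at tRNA and other noncoding genes. With 2179 simulated peaks of which 67.6% were shared, the overlap gave 68.2%. With 20 words of 6 bases, each planted in a small share of 2179 windows, 12 were called, and 0 were called with none planted. A planted log2 signal difference of 0.5 was recovered as 0.609. For the list tests on 19973 genes, all 11 planted lists and 0 of the others were called. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.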

Results

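Chromatin immunoprecipitation with sequencing was used to find where EFL-1, a worm transcription factor of the E2F family, sat on the genome of Caenorhabditis elegans. The animals were whole young adult hermaphrodites of strain YL479, which carry EFL-1 with a C-terminal GFP-FLAG tag, and chromatin was pulled down after sonication with an anti-GFP antibody per the sample descriptions, while the antibody label of the samples reads efl-1. There was 1 group of 2 biological replicates. The measurements were peak lists on build ce11, each peak with a position, a summit and a signal value given by the authors. The lists hold no read counts, so the depth of each replicate is unknown, and input and control libraries were not analysed here. The design asks where EFL-1 was bound, how well the replicates matched and which genes lay at the bound sites.

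The strongest nuclear EFL-1 peaks lay near the starts of cdc-48.1, rpl-3, tasp-1 and rpl-35. The strongest nuclear peak lay on chromosome II from 10563427 to 10563721, in intergenic sequence 162 bp upstream of cdc-48.1, which encodes an AAA ATPase that extracts ubiquitinated proteins. Its signal value was 1895 in the pooled list, 1265 in replicate 1 and 634 in replicate 2. Next came rpl-3, a large ribosomal subunit protein gene, with a peak on chromosome III from 3867401 to 3867723 and a signal value of 1743, then tasp-1, a threonine aspartase gene, with 1623, and rpl-35, another ribosomal protein gene, with 1264. Other genes next to the strongest peaks were rib-2 with 859.6, T23F6.3 with 819, the alpha-tubulin gene tba-2 with 790.0, the translocon subunit gene sec-61.G with 733, fbxl-2 with 658, Y53F4B.11 with 655, citk-2 with 644, the importin beta family gene imb-3 with 642 and the cytochrome oxidase subunit gene cox-5A with 629. All 13 nuclear peaks among the 20 with the highest signal lay within 500 bp of a protein-coding gene start, and the other 7 lay on the mitochondrial genome.

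The authors' optimal IDR-thresholded list, whose peaks are called reproducible here, held 2207 peaks, of which 2179 were on the nuclear chromosomes. Their median width was 276 bp, which 1636 of the 2207 had exactly, as did 29429 of the 30000 pooled candidates. It is therefore no measure of the size of a bound site. The median signal value of the reproducible peaks was 81.1, with 45.6 as the lowest. The list was the same as the 2207 strongest of the 30000 pooled candidate peaks, and no test applies to this number. Counts, positions and tests from here on use the 2179 nuclear peaks. Of these, 1513 (69.4%) overlapped one of the strongest 2179 nuclear candidates in both replicates, so the name does not mean that each peak ranked high in both.

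The strongest peaks of the pool stood high in both replicates. Among nuclear candidates, the peak at cdc-48.1 ranked 1 in replicate 1 and 2 in replicate 2, that at rpl-3 ranked 2 and 3, that at tasp-1 ranked 3 and 1, and that at rpl-35 ranked 4 in both. The peak at efl-1 itself ranked 30 and 86. Of the 2179 strongest nuclear candidates of replicate 1, 1532 (70.3%) overlapped one of the 2179 strongest of replicate 2 by at least 1 bp. Random placement within chromosomes gave 1.16% on average and 2.16% at most (one-sided permutation p = 0.000999, the smallest that 1000 placements can give). Of the candidates ranked 1 to 500 in replicate 1, 98.8% overlapped one of the strongest 2179 of replicate 2. Overlap with any candidate of replicate 2 fell with rank, from 99.4% for ranks 1 to 500 to 93.6% for ranks 1001 to 2000, 66.3% for ranks 2001 to 5000 and 25.5% for ranks 20001 to 29968.

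Signal values followed each other across the reproducible peaks. A candidate was matched in both replicates for 2147 peaks, and their signal gave a Spearman rho of 0.663 and a Pearson r of 0.739 on the log2 scale. These values are across peaks, which are not independent replicates, so no p is given. Signal was higher in replicate 1 by a median of 1.70-fold, and the scale of the signal value is not given in the sources used here, so this ratio has no reading as occupancy.

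**Figure D1:**
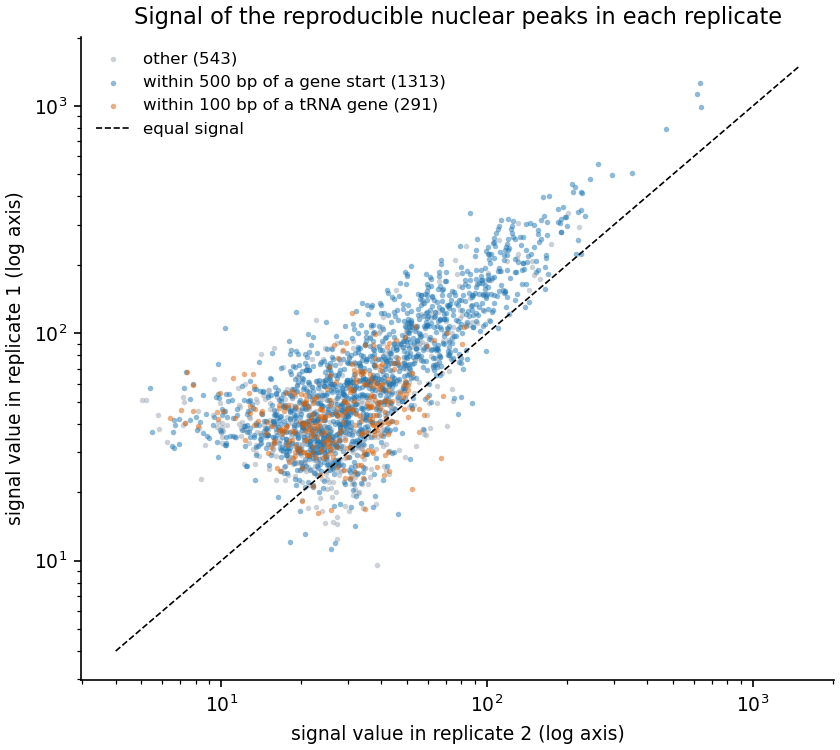
Signal value of each of 2147 reproducible nuclear peaks in replicate 2 (horizontal) and replicate 1 (vertical), both on log axes without units, coloured by position. Most points lie above the dashed line of equal signal (median ratio 1.70), and the strongest peaks are near gene starts.

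EFL-1 was bound at the genes of its own complex. DREAM joins an E2F factor and its partner to a retinoblastoma-like protein and the MuvB core, and 6 of the 10 listed members of DREAM and the E2F family had a peak (60%, 95% Wilson interval 31.3 to 83.2%), against 8.86% of all protein-coding genes (odds ratio 15.5; Fisher's exact test, adjusted p = 0.000147 over 22 lists). The efl-1 gene lies on chromosome V from 16958590 to 16965675 on the minus strand. Its peak spanned 16965731 to 16965954, in intergenic sequence with the summit 171 bp upstream of the gene start, and had a signal value of 440 in the pool, 313 in replicate 1 and 125 in replicate 2. The MuvB core genes lin-53, lin-54 and lin-9 had peaks of 468, 454 and 435, the retinoblastoma-like gene lin-35 one of 226, and dpl-1, which encodes the partner of EFL-1, one of 111.7.

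An E2F-type sequence stood within 100 bp of the summit at efl-1, lin-9, lin-53 and lin-54, but not at lin-35 or dpl-1. The peak of lin-54 was shared with the divergent gene rpl-12, that of lin-53 with nra-2 and that of lin-35 with vps-51. Neither lin-37 nor the E2F genes efl-2 and efl-3 had a reproducible peak or a pooled candidate within 500 bp. For lin-52 the highest candidate had a signal value of 37.6, below the lowest reproducible peak, and unc-119 had 18.7. With the strongest 2179 candidates of either replicate alone lin-52 was bound, and the odds ratio of the list was 23.9 with replicate 1 and 25.98 with replicate 2. It was 26.9 with the stronger 50% of the peaks, 8.65 at 200 bp and 13.7 with the nearest start alone. The summit of the lin-54 peak was 357 bp from the start of lin-54 but 36 bp from that of rpl-12.

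EFL-1 sat just upstream of annotated gene starts. Of the nuclear peaks, 1386 (63.6%, Wilson interval 61.6 to 65.6%) had their summit within 500 bp of a protein-coding gene start, against 23.0% of randomly placed summits (one-sided permutation p = 0.000999, the smallest possible with 1000 placements) and 28.2% of the pooled candidates that overlap no reproducible peak. The summit was upstream of the nearest start for 88.5% of these peaks, at a median of 154 bp upstream. These are the starts of the gene models, and sites where transcription begins were not measured. Of the other 793 peaks, 492 were intergenic, 247 in introns, 32 in untranslated exons and 22 in coding exons. With a distance of 200 bp the share near starts was 38.1%.

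Many of the peaks away from protein-coding starts lay at transfer RNA (tRNA) genes. These genes, which RNA polymerase III transcribes, were examined after the positions of the peaks had been seen. A peak summit lay within 100 bp of 317 of 612 nuclear tRNA genes (51.8%, Wilson interval 47.8 to 55.7%), and 300 peaks were placed so, against 3.18 on average at random (permutation p = 0.000999, the smallest possible). Of the 793 peaks far from protein-coding starts, 244 were at tRNA genes. Peaks at tRNA genes had a median signal value of 69.6, and none was among the 20 strongest nuclear peaks. Small nucleolar RNA genes had a peak at 67 of 346 (19.4%), small nuclear RNA genes at 9 of 129 and microRNA genes at 7 of 261. The peaks there numbered 66, 10 and 7, against 2.75, 0.918 and 1.53 on average at random. The highest random numbers were 10, 5 and 7, so for microRNA genes random placement reached the observed number. Many tRNA genes have identical copies, and how reads that fit several copies were treated is not given in the sources used here.

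Protein-coding genes on the X chromosome were rarely bound. A peak lay at 2.12% of X-linked genes, against 9.93% of autosomal genes (odds ratio 0.197; Fisher's exact test, p = 1.58e-53). Chromosomes III and I had the highest shares, with 14.8% and 14.04% of genes bound. Of all nuclear peaks, 244 (11.2%) were on X, where 13.7% of protein-coding genes lie (odds ratio 0.796; two-sided Fisher's exact test, p = 0.00118). The tRNA genes weighed on this number, since 276 of the 612 are on X and 147 of the 244 peaks on X were at one. Without peaks at tRNA genes, a choice made after seeing the data, 97 of 1879 peaks were on X (5.16%; odds ratio 0.344; Fisher's exact p = 4.05e-31). Against pooled candidates outside the reproducible peaks, 10.9% of which were on X, the odds ratio was 1.03 (Fisher's exact p = 0.695). With peaks and candidates at tRNA genes left out of that comparison, also a choice made after seeing the data, it was 0.450 (Fisher's exact p = 5.90e-17).

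**Figure D2:**
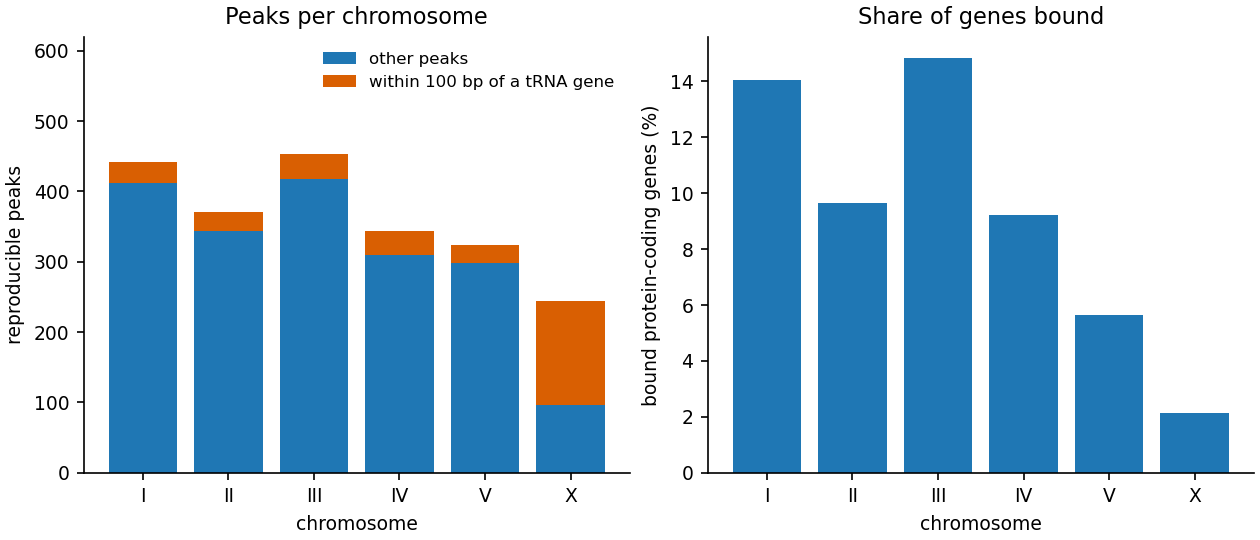
Left, number of reproducible peaks on each nuclear chromosome, split into peaks within 100 bp of a tRNA gene and other peaks; right, percentage of the protein-coding genes of each chromosome with a peak within 500 bp of a start. X has 147 peaks at tRNA genes and 97 others, and 2.12% of its genes were bound.

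The E2F sequence marked a minority of the peaks. TTTSSCGC, where S is C or G, stood within 100 bp of the summit in 374 of 2179 peaks (17.2%, Wilson interval 15.6 to 18.8%), against 4.55% of the 27723 pooled candidates outside the reproducible peaks (odds ratio 4.35; Fisher's exact test, adjusted p = 2.79e-94 over 4 strings). The peaks at top-2, pcn-1 and mcm-4 in DNA replication, at fcd-2 in DNA repair and at mex-1 and cpg-2 in oocytes held it. The shorter TTSSCGC was in 30.7% of peaks against 8.94%. Sites within 50 bp of the summit were 7.57 times as many as sites 450 to 500 bp away, and for the reversed string CGCSSTTT the ratio was 4.25. That string, the control for base composition, was also more frequent in peaks (5.32% against 1.71%; odds ratio 3.23; Fisher's exact adjusted p = 1.11e-22). Among the 420 rearrangements of the same letters that keep a CG step, TTTSSCGC was first by share of peaks and ranked 3 by odds ratio, and the median odds ratio was 1.56. With windows of 250 bp either side the odds ratio of TTTSSCGC was 2.62.

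Stronger peaks held the E2F sequence more often. It was in 31.4% of the 545 strongest peaks (Wilson interval 27.6 to 35.4%), among them those at rib-2, T23F6.3, tba-2, fbxl-2 and Y53F4B.11, and in 15.8%, 10.3% and 11.2% of the following 3 groups of equal size. Mean log2 signal was 6.99 (SD 1.01, n = 374 peaks) with it and 6.45 (SD 0.80, n = 1805 peaks) without it, a difference of 0.54 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). The strongest peaks were not all of this kind: those at cdc-48.1, tasp-1, sec-61.G and imb-3 held the shorter sequence, and those at rpl-3, rpl-35, citk-2 and cox-5A held neither.

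**Figure D3:**
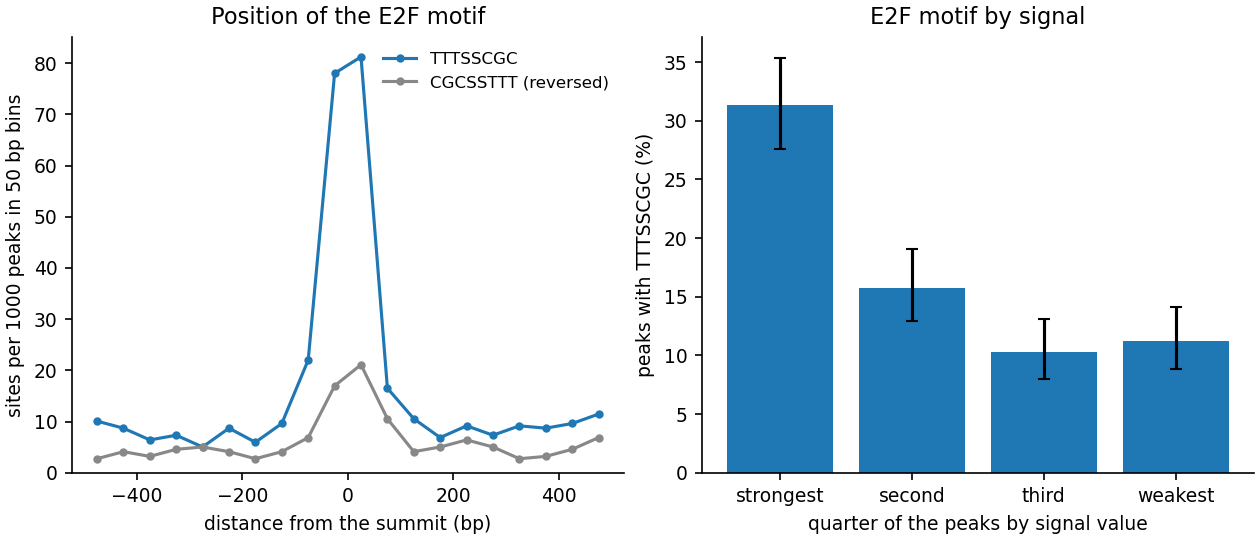
Left, sites of TTTSSCGC and of its reversed string per 1000 peaks in bins of 50 bp against the distance from the summit in bp; right, percentage of peaks with TTTSSCGC within 100 bp in 4 groups of peaks ordered by signal value, with 95% Wilson intervals. The sequence is concentrated within 50 bp of the summit and is in 31.4% of the strongest group and 11.2% of the weakest.

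The cell cycle gene homology region is the sequence TTYGAA bound by the DREAM subunit LIN-54. Before GC content was taken into account, it differed little between peaks and other candidates. It stood near 56.4% of summits against 53.6% (Y is C or T; odds ratio 1.12; Fisher's exact test, adjusted p = 0.0125), while the reversed string AAGYTT was less frequent in peaks (27.3% against 34.5%; odds ratio 0.715; Fisher's exact adjusted p = 8.43e-12). Near gene starts, in peaks and candidates alike, 61.8% of peaks and 52.3% of candidates held TTYGAA (odds ratio 1.48; Fisher's exact p = 5.48e-11).

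Sequences rich in CG steps stood out in a scan of all 2080 six-letter words. The 10 with the highest odds ratio against windows 500 bp away were CGCGCG, GCGCGC, ACGCGC, CGCGCC, CGCGCA, CCGCGC, CCCGCG, AGCGCG, GCGCGA and GCGCCA. CGCGCG was in 14.1% of peaks and 1.10% of flanking windows (odds ratio 14.7; Fisher's exact adjusted p = 7.88e-99), and GCGCCA, part of the reverse complement of an E2F site, in 19.1% and 4.04% (odds ratio 5.61; Fisher's exact adjusted p = 1.43e-80). In all, 562 words were more frequent in peaks and 665 in flanks at an adjusted p under 0.05. Mean GC content was 40.8% in peak windows and 37.3% in flanks, so words of G and C are favoured by composition.

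EFL-1 was bound at 1770 of 19973 nuclear protein-coding genes (8.86%), counting a gene as bound when a summit lay within 500 bp of one of its starts. A peak could serve several genes, as that between top-2 and the nuclear pore gene npp-3 did, and 410 peaks did so. The number was 945 with a distance of 200 bp and 1061 with the stronger 50% of the peaks. Of 22 gene lists chosen before the data were examined, 13 held more bound genes than the rest of the genome, 3 held fewer and 6 did not pass Fisher's exact test at an adjusted p of 0.05. At 200 bp, and against genes with a pooled candidate within 500 bp of a start, 10 lists held more and 3 fewer. Of the 10 against genes with a candidate, DREAM and E2F genes had a higher odds ratio than against all genes, 19.8, and the other 9 lower ones, at 11.3 for segregation, 8.99 for oocyte, 8.77 for cytosolic ribosomal protein, 8.62 for replication, 4.84 for proteasome, 4.51 for cell cycle, 3.54 for germ granule, 3.50 for repair and 3.30 for stem cell genes.

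**Figure D4:**
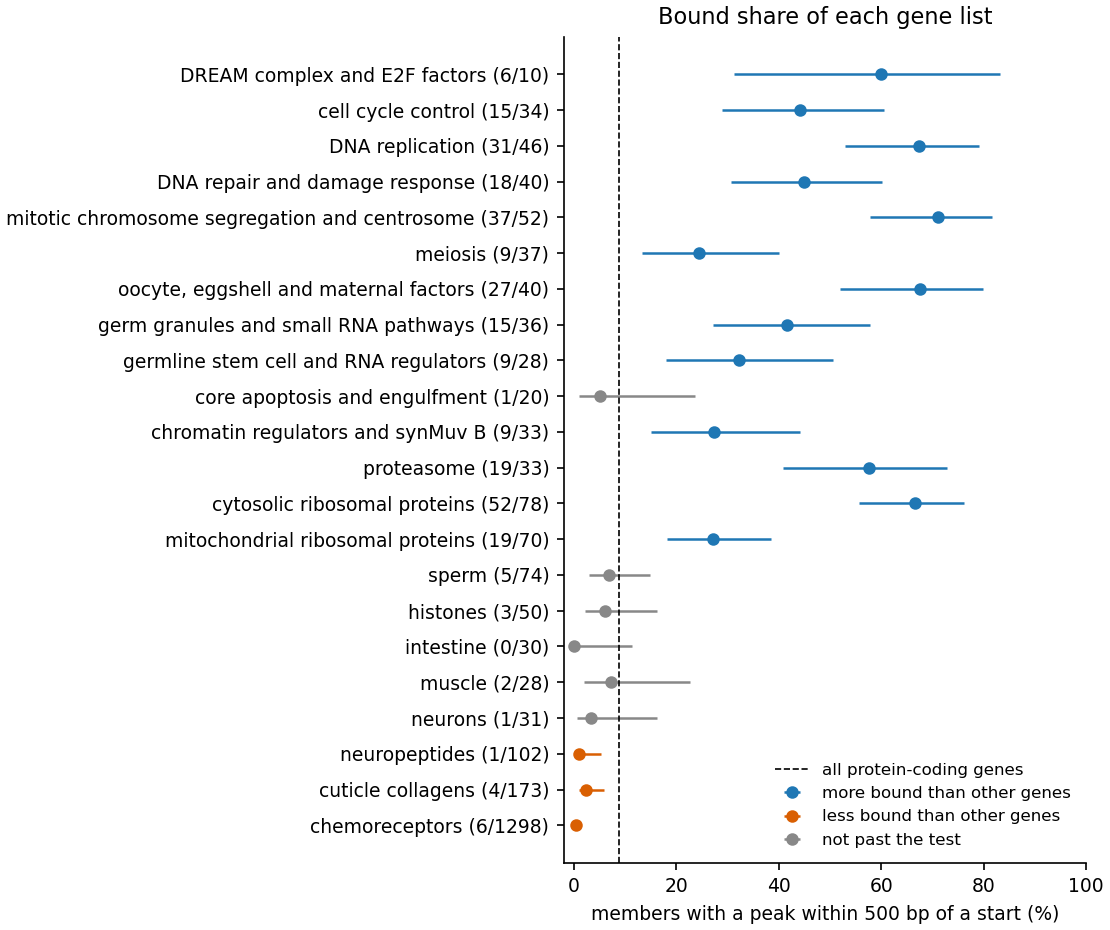
Percentage of the members of each gene list with a peak within 500 bp of a start (points) with 95% Wilson intervals (bars), bound members over all members in parentheses and all protein-coding genes as the dashed line. DNA replication, mitotic segregation, oocyte and cytosolic ribosomal protein genes lie between 66.7% and 71.2%, and chemoreceptors at 0.462%.

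DNA replication and chromosome segregation genes were bound at most of their members. Of 46 replication genes 31 had a peak (67.4%, Wilson interval 53.0 to 79.1%; odds ratio 21.6; Fisher's exact adjusted p = 1.39e-21). The highest signal values were 557 at top-2, a topoisomerase gene, 491 at mcm-2 and 341 at mcm-4, which encode parts of the replicative helicase, and 399 at pcn-1, the PCNA gene. The mcm-2 peak on chromosome II spanned 12006742 to 12006965, in intergenic sequence 227 bp upstream of the start. Of 52 mitotic segregation and centrosome genes 37 had a peak (71.2%, interval 57.7 to 81.7%; odds ratio 25.9; Fisher's exact adjusted p = 7.07e-27), with an odds ratio of 51.6 at 1000 bp and 15.01 with the nearest start alone. They were led by the kinetochore gene hcp-1 with 576, the chromosomal passenger gene csc-1 with 402, the kinetochore gene knl-3 with 362 and the centrosome gene spd-2 with 276. TTSSCGC stood at 26 of the 34 peaks of replication genes and 22 of the 38 of segregation genes.

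Cell cycle and DNA repair genes also held more peaks than other genes. Of 34 cell cycle regulators 15 had a peak (44.1%; odds ratio 8.18; Fisher's exact adjusted p = 1.55e-07), with 438 at the inhibitory kinase gene wee-1.3, 386 at the Polo kinase gene plk-1, 309 at the cyclin B gene cyb-3 and 229 at cyb-1. With a distance of 200 bp this list no longer passed (odds ratio 2.69; Fisher's exact adjusted p = 0.110). Of 40 repair and damage response genes 18 had a peak (45%; odds ratio 8.49; Fisher's exact adjusted p = 5.56e-09), led by hpr-17 with 353, fcd-2 with 345, polh-1 with 309 and smc-5 with 244. The polh-1 peak was shared with the ribosomal protein gene rps-22, and the cyb-1 peak with orc-5.

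Oocyte, maternal and other germline genes were among those with many peaks. Of 40 oocyte, eggshell and maternal genes 27 had a peak (67.5%, Wilson interval 52.02 to 79.9%; odds ratio 21.7; Fisher's exact adjusted p = 5.39e-19), and at 200 bp the odds ratio was 11.0 (Fisher's exact adjusted p = 8.27e-09). The CCCH zinc finger gene mex-1 had a peak of 440 on chromosome II from 11968364 to 11968574, the eggshell proteoglycan gene cpg-2 one of 389, the yolk receptor gene rme-2 one of 361 and mex-5 one of 348. Germ granule and small RNA genes had a peak at 15 of 36 (41.7%; odds ratio 7.4; Fisher's exact adjusted p = 3.48e-07), with 302 at glh-2, a Vasa-like helicase gene, 211 at ppw-1, 199.8 at hrde-1 and 171 at rde-4. Germline stem cell and RNA regulators had one at 9 of 28 (32.1%; odds ratio 4.89; Fisher's exact adjusted p = 0.000882), at most 113 in signal value (rnp-8), followed by atx-2, gld-2 and nos-2 with 108, 104.4 and 102.

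Meiosis genes were bound at 9 of 37 (24.3%; odds ratio 3.32; Fisher's exact adjusted p = 0.00576). The cohesin genes rec-8, coh-4 and coh-3 had peaks of 348, 284 and 153, and the katanin subunit gene mei-2 one of 308. All of these peaks were shared with another gene. The rec-8 peak was the same as that of mex-5 in the oocyte list, and the coh-3 peak as that of bmk-1 in the segregation list. That of coh-4 was shared with pid-5 and that of mei-2 with syp-6. With each peak given to its nearest start alone, the meiosis list had an odds ratio of 2.65 (Fisher's exact adjusted p = 0.0519), and against genes with a pooled candidate at a start it had an odds ratio of 1.18 (Fisher's exact adjusted p = 0.793). Chromatin regulators were bound at 9 of 33 (27.3%; odds ratio 3.87; Fisher's exact adjusted p = 0.00263), with 355 at mes-2 and 219.8 at mes-6, which encode parts of the worm Polycomb complex, 204 at mrg-1 and 180 at set-2. That list did not pass against genes with a candidate (odds ratio 1.98; Fisher's exact adjusted p = 0.209) or at 200 bp (odds ratio 2.78; Fisher's exact adjusted p = 0.108).

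Genes of protein synthesis and breakdown were also bound. Of 78 cytosolic ribosomal protein genes 52 had a peak (66.7%, Wilson interval 55.6 to 76.1%; odds ratio 21.2; Fisher's exact adjusted p = 3.60e-35), led by rpl-3 and rpl-35, then rpl-20 with 463 and rpl-12 with 454 (shared with lin-54). Their peaks stood farther upstream of annotated starts than those of replication genes, at a median of 294 bp against 151 bp (a difference that was not tested). Of the 52 bound genes, 6 had a summit within 200 bp. At that distance the list did not pass (odds ratio 1.68; Fisher's exact adjusted p = 0.256), and the odds ratio was 10.8 with the nearest start alone and with the stronger 50% of the peaks. TTSSCGC stood at 5 of the 51 ribosomal protein gene peaks. Of 33 proteasome genes 19 had a peak (57.6%; odds ratio 14.1; Fisher's exact adjusted p = 8.20e-12), with 428 at rpn-11, 277 at rpn-6.1, 242 at pas-5 and 193 at rpt-1, and the odds ratio was 8.84 at 200 bp and 8.995 with the stronger 50% of the peaks. Mitochondrial ribosomal protein genes had one at 19 of 70 (27.1%, odds ratio 3.86, Fisher's exact adjusted p = 1.56e-05), with 229 at mrps-16, 221 at mrpl-47, 213 at mrpl-28 and 199.6 at mrpl-55. With the stronger 50% of the peaks the odds ratio of that list was 2.31 (Fisher's exact adjusted p = 0.0465). It did not pass against genes with a candidate (odds ratio 1.69, Fisher's exact adjusted p = 0.124).

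Chemoreceptor, neuropeptide and collagen genes were bound less often than other genes. Chemoreceptor genes had a peak at 6 of 1298 (0.462%; odds ratio 0.0445; Fisher's exact adjusted p = 2.66e-43), neuropeptide genes at 1 of 102, which was flp-23 with 52.2 (odds ratio 0.101; Fisher's exact adjusted p = 0.00219), and cuticle collagen genes at 4 of 173 (odds ratio 0.242; Fisher's exact adjusted p = 0.00119). Several of these peaks also lay within 500 bp of the start of a gene of another kind: sri-5 with 281 beside rsr-1, srd-4 with 89.04 beside usip-1, col-38 with 195 beside the ribosomal protein gene rpl-5 and col-2 with 101.4 beside the kinetochore gene ndc-80. The peaks of srh-269 (116), col-85 (115.4) and flp-23 were at tRNA genes, and the fourth collagen gene was col-71 with 69.4. With replicate 2 alone neither flp-23 nor col-71 was bound. With replicate 1 alone the odds ratio was 0.203 for neuropeptides (Fisher's exact adjusted p = 0.0112) and 0.0293 for chemoreceptors (Fisher's exact adjusted p = 1.51e-46). Against genes with a candidate the odds ratio of chemoreceptors was 0.187 (Fisher's exact adjusted p = 2.62e-06). With the stronger 50% of the peaks the collagen list had an odds ratio of 0.313 (Fisher's exact adjusted p = 0.0525).

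The remaining lists did not pass Fisher's exact test. Intestine genes had a peak at 0 of 30, with a Wilson interval of up to 11.4% (Fisher's exact adjusted p = 0.138), and muscle genes at 2 of 28, unc-45 with 91.5 and unc-112 with 55.1 (adjusted p = 1). Neuronal genes had one at 1 of 31, ric-19 with 85.96 (Fisher's exact adjusted p = 0.635), and sperm genes at 5 of 74 (adjusted p = 0.750), among them spe-39 with 218, shared with the maternal gene spn-4, spe-47 with 94.5, spe-9 with 89.3, at a tRNA gene, and spe-48 with 79.2. Histone genes had one at 3 of 50 (Fisher's exact adjusted p = 0.721), his-37 with 163 and the pair his-67 and his-68 with 57.8. Core apoptosis and engulfment genes had one at 1 of 20, cep-1, the worm p53 gene, with 49.3 (Fisher's exact adjusted p = 1). Of these genes cep-1 was not bound with replicate 2 alone, nor unc-112 with replicate 1 alone. A list that did not pass is not shown to be bound at the same share as other genes, and the histone genes have near-identical copies.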

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

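The coverage test below was chosen after the result was seen. The nuclear comparisons leave out 28 peaks on the mitochondrial genome, which drew attention because they are more than the 3 that a count of 0 allows and hold the highest signal values of the list. The highest was 4115, against 1895 for the strongest nuclear peak, and 7 of the 20 strongest peaks were mitochondrial. They had 14 distinct intervals on a genome of 13794 bp. The strongest spanned positions 3127 to 6466, which held summits of 4115, 702 and 654, and 11897 to 13355, which held summits of 2446 and 1816; the other intervals among the top 20 were 1732 to 2616 with 1093 and 7296 to 10097 with 774.

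E2F sites in mitochondrial DNA are argued against: TTSSCGC was in 1 of 28 mitochondrial windows (3.57%) against 30.7% of nuclear peaks (Fisher's exact p = 0.000693). The 28 windows come from 14 intervals of 1 genome and are not independent, so the p is nominal. Base composition was not taken into account. Coverage of abundant mitochondrial DNA stays open as a candidate explanation, since the mitochondrial peaks among the strongest 2207 candidates covered 93.9% of that genome in replicate 1 and 65.1% in replicate 2. No input library was analysed here, and no biological explanation was tested.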

How the results depend on the processing

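Of 71 alternative values for the results that answer a comparison, 66 were kept. A test was kept if it held its direction and its side of the threshold, and a count if it stayed within 1.5 times. The Spearman rho was kept if it moved by less than 0.0148, its SD over 1000 bootstrap draws of peaks. Leaving out tRNA peaks or candidates, stratifying by GC content and counting nuclear peaks alone were chosen after seeing the data. The stronger 50% of the peaks are 1103 by construction, with 1061 bound genes, and the Spearman rho between replicates was 0.682 in them. A distance of 200 bp gave 945 bound genes, fewer by construction. Against candidates the odds ratio of X was 1.03 (Fisher's exact p = 0.695), to the other side of 1 from 0.796, and with tRNA genes left out of peaks and candidates it was 0.450 (Fisher's exact p = 5.90e-17).

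A replicate alone was taken as its strongest 2179 nuclear candidates. The number of peaks was thus fixed in advance, which limits how far the number of bound genes could move. Each replicate alone gave an odds ratio of 0.745 to 0.815 for X, 60.9% to 64.1% of peaks near starts, an odds ratio of 4.30 to 4.96 for the E2F motif and 1.14 to 1.15 for CHR, a log2 signal difference of 0.52 to 0.54, 1652 to 1785 bound genes, 13 enriched lists and 3 depleted lists. Of the 1652 genes with replicate 2 alone, 1457 were among the 1770, and of the 1785 with replicate 1 alone, 1622. The share of top candidates shared by the replicates was 59.6% to 75.02% over 4 alternatives. The E2F odds ratio was 2.62 to 6.48 and that of CHR 1.12 to 1.61 over their alternatives, with 3.94 and 1.61 when stratified by GC content.

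Of 176 values for single lists, 8 lost their call and 5 lay on the other side of 1, none of the 5 past the threshold: apoptosis at 200 bp (odds ratio 1.06), sperm against genes with a candidate (1.17), histones at 1000 bp (1.5), and muscle with the nearest start alone (1.05) and with replicate 2 alone (1.33, against 0.377 with replicate 1). The cause was not tested. For 95 named genes, 590 of 665 values kept the call, 73 lost it and 2 gained one, both lin-52; 40 of the losses came at 200 bp and 18 with the nearest start alone. No paired analysis was possible because there is 1 group of 2 replicates and no group to compare it with. Depth limits all results in a way that could not be measured, since the lists hold no read counts.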

Other observations

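Among the tests below, that on intestine and muscle genes was chosen after the result was seen. Chromosomes differed in how densely they were bound. Leaving out peaks at tRNA genes, chromosome III had 30.3 peaks per Mb, I 27.3, II 22.5, IV 17.7, V 14.2 and X 5.47. Peaks at tRNA genes were on X at nearly the share of the tRNA genes themselves (49.0% against 45.1%; Fisher's exact p = 0.289).

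Few of the peaks at ribosomal protein and tRNA genes held the E2F sequence. TTSSCGC as what directs binding at most of these peaks is argued against at both: its odds ratio was 0.0594 for ribosomal protein gene peaks against those at replication, segregation and oocyte genes (5 of 51 against 64 of 99; Fisher's exact p = 3.69e-11) and 0.259 for tRNA peaks against other nuclear peaks (Fisher's exact p = 1.87e-16). The 3 lists held it more often than all nuclear peaks, of which 30.7% did, so the value of 0.0594 depends on that choice. Among nuclear peaks away from tRNA genes, 634 of 1879 held it. Its absence therefore does not set the ribosomal or tRNA peaks apart from most others. High transcription as the source of the ribosomal peaks stays open. The intestine and muscle lists together were bound at 3.45% (2 of 58, Fisher's exact p = 1.82e-15 against 52 of 78). No expression was measured and transcription in the germline was not covered, so this share cannot decide the question. Whether shared reads made the tRNA peaks cannot be decided. Of 140 tRNA genes with no second exact copy, 44 had a peak (31.4%, exact binomial interval 23.9 to 39.8%), above the 5% set beforehand. Only exact copies were counted, however, and reads can also be shared between nearly identical genes. Genes with exact copies had a peak more often (57.8%, Fisher's exact p = 5.02e-08). Background at open promoters may account for the ribosomal peaks and stays open. Their odds of the sequence were 1.09 times those of candidates near starts (Fisher's exact p = 0.806), from 5 of 51 peaks, which does not show equal shares. Their mean log2 signal differed by -0.358 from that at the other lists (permutation p = 0.0407). Against genes with a pooled candidate at a start, 52 of 72 ribosomal protein genes had a peak (odds ratio 8.77, Fisher's exact adjusted p = 3.36e-17). Candidates reached down to a signal value of 10.3, so holding one does not match genes for how open their promoters are. That comparison therefore cannot decide the question. Neither an input library nor another factor was analysed here.

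Signal at the tagged gene was examined because extra transgene copies could raise it. The 40 kb centred on efl-1 held 16 pooled candidates, between the median of 11 and the 95th percentile of 25 over 2503 windows of that length. The bound set beforehand was that percentile, but a number of candidates does not measure signal, so the count decides nothing and extra copies stay open.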
